A study of Bacillus subtilis subsp. subtilis str. 168 with 18 samples.

How the data were processed

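RNA levels were measured on 18 two-colour arrays in Bacillus subtilis JH642, a laboratory strain, and in a mutant of it that lacks nsrR. Per the labels, cells grew without oxygen to mid-log phase in 2xYT, a rich tryptone and yeast extract medium, with 1 of 3 treatments. The nitrate cultures received 1% glucose and 0.2% nitrate, and the pyruvate cultures 0.5% glucose and 0.5% pyruvate. The third kind were pyruvate cultures given spermine NONOate, a compound that releases nitric oxide (NO), for 1 h. The labels give its amount as 100 mM. They also give RNA amounts in mg where µg would be usual, so micro signs may have been lost, and the dose is uncertain. RNA was taken with a column kit, copied into aminoallyl cDNA from random hexamers, and labelled with Cy5. An aliquot of every sample was pooled into 1 reference, labelled with Cy3, so that every array set a sample against the same pool. The scanner, the background correction, the normalization and the software were not given in the sources used here.

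The deposited values are log ratios of the sample over the pool, 1 column per array, for 4109 probe IDs, and were taken as log2. Neither the log base nor the direction is written in the table. Per the labels the sample carries Cy5 and the reference Cy3, and the values were tested against a property of a pool. Under the right base and direction, the linear ratios of a probe should average about 1 over the pooled samples, at any spread, if the ratios are undistorted. Log values were averaged within each of the 6 groups first, and the linear ratios of the groups were then averaged. The base that left no trend of this mean with spread was 1.85 (95% bootstrap interval 1.75 to 1.95, 1000 resamples of probes). In the log2 of this mean, base 2 left a difference of 0.06 between the 2% of probes with the widest spread and the lower 50% of probes. Base e left 0.32 and base 10 1.65. With the direction turned, base 2 left 1.23. Base 2 was the nearest of these bases, and every log2 difference and every count of 2-fold changes rests on it, while the calls do not. The interval leaves out 2 itself. Either the base is not 2 or the property did not hold exactly, so the base is an inference from the values. Centring is likewise unstated. The array medians, averaged per group, were 0.02 (SD 0.06) for wild type in pyruvate, −0.08 (SD 0.01) with NO and −0.01 (SD 0.03) in nitrate. For the mutant they were −0.17 (SD 0.02), −0.17 (SD 0.03) and −0.13 (SD 0.02), each over 3 arrays, so the arrays were not centred on a common median.

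The probe IDs were not paired with genes in any table used here: 0 of the 4109 IDs were found in the gene table, and no name was inferred from an ID. Lists of genes fixed before the data were examined, with their tests and estimated-correlation repeats, therefore have no result, and nsrR itself and other genes chosen beforehand could not be looked up. No probes of 1 gene could be averaged, so each probe stood alone. Control spots could not be told from others. The rule for named items, fixed beforehand, took those with the largest rises and falls among calls with an adjusted p under 0.05 whose groups did not overlap on any array, or with the adjusted p alone for the 2 interactions. From that order only the first 2 IDs in each direction are named per comparison. Sets of probes were otherwise described by their calls.

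Of the table's cells 24.3% held no value, 305 probes held none on any array, and 1836 held one on all 18. The number of probes with a value ran from 2538 to 3555 per array. Probes with at least 2 values in each of the 6 groups were tested, 2765 in all (67.3% of the IDs); the other 1344 were not. The number of arrays, 3 per group, limits the precision, and a permutation test of 3 against 3 cannot go below p = 0.1. The columns of 3 wild-type arrays (nitrate 1 and 2, pyruvate 1) were rounded to 2 decimals while the others carried more digits, and these were treated as a possible processing batch.

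Arrays were grouped by the genotype and treatment in their titles. One linear model with 6 group means was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend), which shares 1 estimate of the spread. Calls are two-sided, at a Benjamini-Hochberg adjusted p under 0.05 over the probes of a comparison, and counts with at least 2-fold change (a log2 difference of 1) are given beside them. The 9 planned comparisons were the mutant against wild type in each treatment, NO and nitrate against pyruvate in each genotype, and the difference of each of these effects between genotypes. NO against nitrate was added after the data were examined. The design text speaks of biological triplicates, and p-values measure the spread between those cultures, taken as independent.

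Within 1 group the arrays correlated across all probes with a median r of 0.73 (18 pairs, 0.53 to 0.88), and arrays of the other genotype under the same treatment with 0.59. This order did not hold in every group. Mutant arrays had a median of 0.55 among themselves in nitrate and 0.61 with NO, against 0.64 and 0.67 with wild-type arrays. In mutant pyruvate arrays (0.71 against 0.53) and in all wild-type groups the median within the group was the higher. Arrays of different treatments correlated with a median of −0.11 within a genotype (12 of 54 pairs under −0.3) and −0.19 across genotypes (23 of 54 pairs under −0.3, lowest −0.59). The dyes are stated and treatments measured against their own pool can oppose, so the direction was kept.

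Replicate numbers in the titles were checked as pairs before the calls of paired fits were compared. Deviations of arrays from their group means, across probes, correlated between same-numbered arrays of 1 genotype with a median r of 0.33 (0.10 to 0.55, 17 of 18 pairs over 0.1). Between genotypes the same number gave a median of −0.06, with 5 of 27 pairs over 0.1. The numbers thus paired the arrays of 1 genotype, for NO against pyruvate and nitrate against pyruvate in both, and not across genotypes. Pairs with different numbers across genotypes had a median of 0.04 (−0.43 to 0.40), with 18 of 54 over 0.1. Some arrays with different numbers thus shared deviations across genotypes. What this does to comparisons of the genotypes was not tested. A random block for genotype and number had a correlation of 0.22. The SEs and p-values given below come from the fit without this block, unless another fit is named, and so leave the pairing out.

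The fit was tested on simulated data built on the spread of these arrays: of 2765 probes, 200 were changed for NO against pyruvate in wild type. It called 58.3% of those changed by log2 0.5, 97.1% at 1 and 100% at 2, and 11 of 184 calls (5.98%) were of unchanged probes. In NO against pyruvate in the mutant, where nothing was changed, it called 0. The simulated noise was independent between arrays and between probes and held no array offsets, unlike these arrays. The rates of false calls may therefore not hold for the real data. Overlaps between comparisons that share the same 3 arrays were set beside 100 simulations of unchanged groups against shared controls, and 100 more, added after the data were seen, with the block correlation of 0.22. Alternatives were median centring, quantile normalization, robust eBayes, array quality weights, a replicate block, only the compared groups, probes measured on all arrays, dropping the probes with the smallest spread, and leaving out each array. Others, chosen after seeing the data, were a block within genotype, a looser requirement on missing values, and fits by or without the rounded arrays. Figures were drawn with matplotlib 3.10.9.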

Results

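Two-colour arrays compared transcript levels of anaerobic Bacillus subtilis cultures of 2 genotypes under 3 treatments, with 3 arrays in each of the 6 groups. Wild type was strain JH642, and the mutant lacked nsrR, which encodes a transcriptional repressor with an iron-sulfur cluster that reacts with nitric oxide (NO). Cells respiring nitrate make NO themselves, cells fermenting glucose and pyruvate are taken not to, and the third treatment added an NO donor to the fermenting cells. Each value is the log2 ratio of a sample over a pool of all samples, for 2765 tested probes out of 4109. The log base is an inference from the values. The number of arrays, 3 per group, limits the precision. Probes are given by their IDs, because the sources used here do not pair them with genes, so the deleted gene could not be followed in these samples. The median SD between the 3 arrays of a group ran from 0.12 in wild type in nitrate to 0.18 in the mutant with NO.

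The first question was how the mutant differed from wild type in pyruvate cultures, without added NO or nitrate. Probe BSO8-585 lay far below the pool in wild type, at −6.66 ± 0.09 (SD, n = 3), and stood at 0.26 ± 0.31 (SD, n = 3) in the mutant, so that it rose by 6.92 ± 0.17 (log2, SE). Its wild-type level was 0.99% of the pool, and the −6.75 on array 1 was the lowest value of all arrays. Signal over background was not given, so how far a floor set the size of this rise is unknown. The same limit holds for its rises with NO and nitrate and for other probes this low. BSO8-827 rose from −2.90 ± 0.16 to 0.94 ± 0.36 (SD, n = 3), a difference of 3.84 ± 0.15 (SE). BSO8-2159 fell from 0.73 ± 0.28 to −2.73 ± 0.64 (SD, n = 3), a difference of −3.46 ± 0.25 (SE), and BSO8-515 differed by −1.91 ± 0.24 (SE). The limma adjusted p-values of these 4 probes were 9.58e-14, 2.56e-11, 1.21e-07 and 0.000126. As the rule for naming required, every mutant array lay beyond every wild-type array, which held at 1103 of all 2765 probes. The median of all tested probes was itself lower in the mutant by a shift of −0.19, and with each array centred on its own median the 4 differences were 7.12, 4.04, −3.26 and −1.71.

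Of the 2765 probes, 447 were called in this comparison, 78 higher and 369 lower in the mutant, and 37 and 36 of these differed by at least 2-fold. With each array centred on its median, 160 were called, 116 higher and 44 lower, of which 122 were among the 447, and 44 and 6 differed by at least 2-fold. The centring thus set which side had more calls. Quantile normalization left 81 (41 higher, 40 lower), and a fit of only the compared groups 186 (53 higher, 133 lower). Without the 3 rounded arrays 91 were called (46 higher, 45 lower), without wild-type array 1 alone 145 (59 higher, 86 lower), and with rounding as a block 212 (64 higher, 148 lower).

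The second question was the response to added NO. In wild type BSO8-1762 rose from −5.74 ± 0.07 to 1.28 ± 0.28 (SD, n = 3), by 7.02 ± 0.26 (SE, adjusted p = 1.51e-11, limma). BSO8-585 rose by 6.77 ± 0.17 (SE, adjusted p = 1.33e-13), to 0.12 ± 0.21 (SD, n = 3). BSO8-823 fell from 0.90 ± 0.17 to −4.63 ± 0.47 (SD, n = 3), a difference of −5.52 ± 0.28 (SE, adjusted p = 3.06e-10), and BSO8-822 by −5.36 ± 0.34 (SE, adjusted p = 3.91e-09). In all, 1065 probes were called, 397 higher and 668 lower, with 133 and 126 changed at least 2-fold. The median of all probes shifted by −0.11. With the arrays centred these 4 differences were 7.13, 6.88, −5.42 and −5.25, and 987 were called, 516 higher and 471 lower, 868 of them among the 1065. Without the rounded arrays of wild type 683 were called.

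The NO donor was given to the mutant as well. BSO8-1762 rose by 5.49 ± 0.26 (SE, adjusted p = 6.67e-10) and BSO8-2450 by 4.60 ± 0.25 (SE, adjusted p = 3.56e-09). BSO8-823 and BSO8-820 fell, with differences of −5.17 ± 0.28 (SE, adjusted p = 3.96e-09) and −5.14 ± 0.35 (SE, adjusted p = 2.72e-08). Calls numbered 1149, 580 higher and 569 lower, with 177 and 143 at least 2-fold. Across probes, which are not independent replicates, the responses of both genotypes correlated with r = 0.88 (rho 0.87), with no array in common. Calls shared by both comprised 372 probes higher and 473 lower, against 83.3 and 137 for independent lists, and 8 probes went opposite ways. Of the 133 probes that rose at least 2-fold in wild type, 128 were called higher in the mutant and 4 lower. Of the 126 that fell at least 2-fold, 121 were called lower in the mutant and 0 higher.

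**Figure D1:**
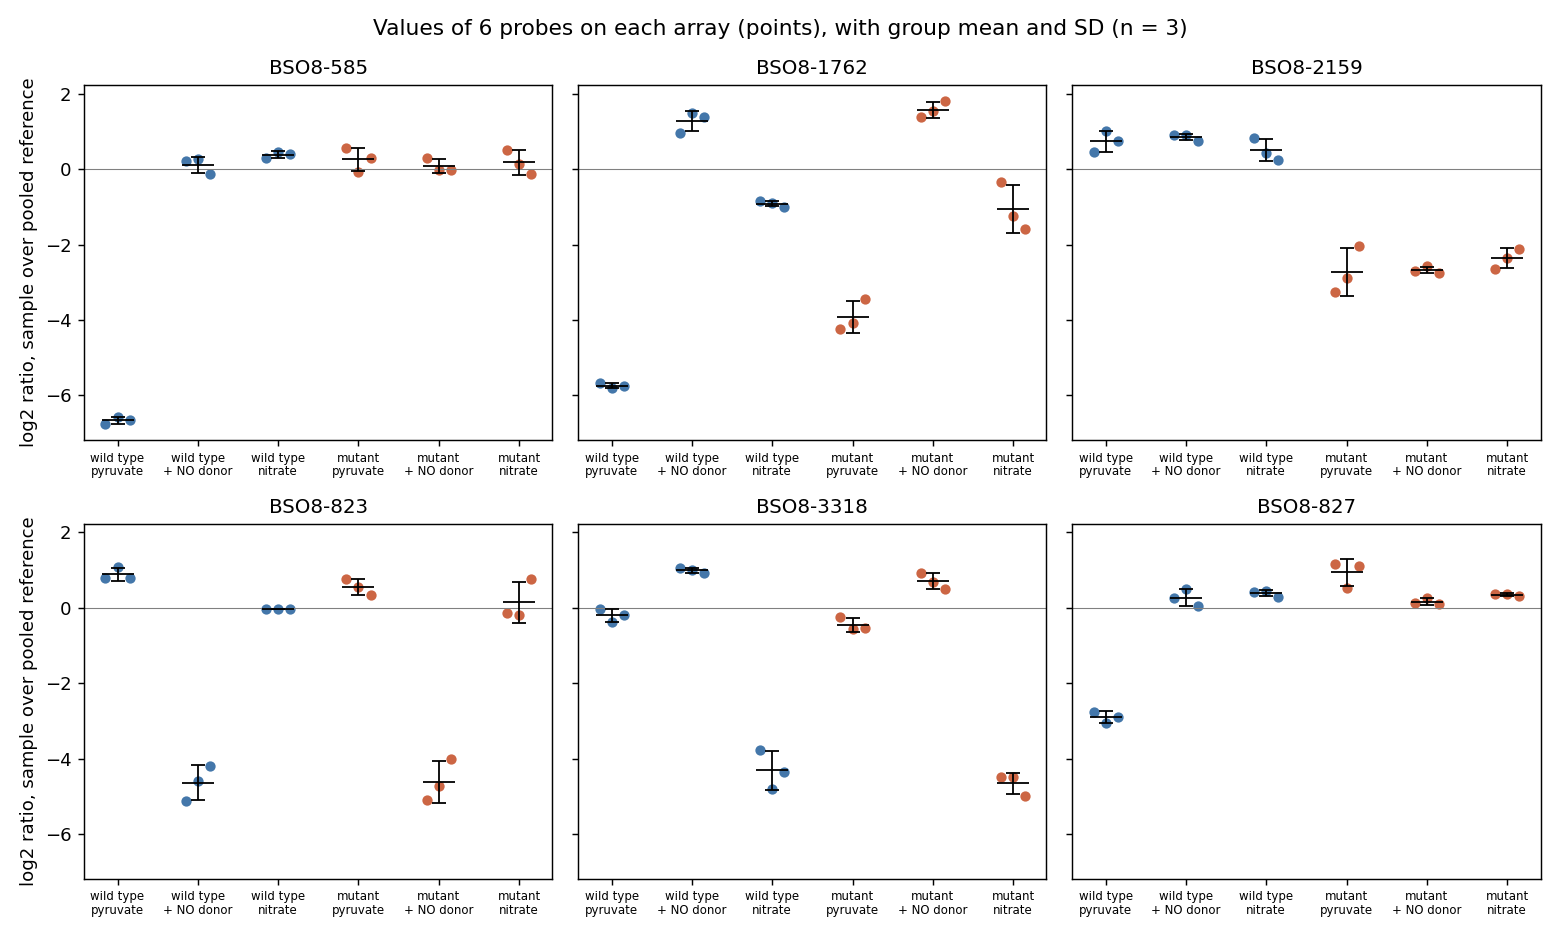
Log2 ratio over the pooled reference (vertical axis) of 6 probes on each array, by genotype and treatment (horizontal axis); points are arrays, and horizontal lines with bars the mean and SD of 3 arrays. BSO8-585 lies at −6.66 in wild type in pyruvate and between 0.09 and 0.38 in the other 5 groups, and BSO8-2159 separates the genotypes under all treatments.

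The third question was the response to nitrate respiration, in which cells make their own NO. The nitrate cultures had 1% glucose and no pyruvate, the fermenting ones 0.5% glucose and 0.5% pyruvate, so in every comparison of nitrate with pyruvate cultures an effect of nitrate cannot be parted from that of the carbon source. In wild type BSO8-585 rose by 7.04 ± 0.17 (SE, adjusted p = 7.27e-14) and BSO8-333 by 5.90 ± 0.28 (SE, adjusted p = 2.5e-10). BSO8-3318 fell from −0.20 ± 0.17 to −4.30 ± 0.52 (SD, n = 3), a difference of −4.11 ± 0.21 (SE, adjusted p = 3.88e-10), and BSO8-3319 by −3.60 ± 0.28 (SE, adjusted p = 8.16e-08). A total of 429 probes were called, 169 higher and 260 lower, with 74 and 83 at least 2-fold. These groups hold rounded and unrounded arrays. With only the rounded ones (nitrate arrays 1 and 2 against pyruvate array 1) 136 were called, and with only the unrounded ones (nitrate array 3 against pyruvate arrays 2 and 3) 192. In each of these 1 side is a lone array, assumed to vary like the other groups, whose pooled spread was used. The differences correlated with r = 0.88 across 2658 probes, and all 114 probes called in both had the same direction.

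In the mutant BSO8-2450 was higher in nitrate than in pyruvate cultures by 3.11 ± 0.25 (SE, adjusted p = 4.87e-07) and BSO8-2451 by 3.03 ± 0.25 (SE, adjusted p = 6.32e-07). BSO8-3318 and BSO8-3319 were lower, with differences of −4.21 ± 0.21 (SE, adjusted p = 3.79e-09) and −3.66 ± 0.28 (SE, adjusted p = 4.87e-07). Calls numbered 620, 349 higher and 271 lower, and 61 and 92 changed at least 2-fold; with the arrays centred, 280 of 605 were higher and 325 lower. The nitrate responses of the genotypes correlated with r = 0.75 (rho 0.68). Shared calls comprised 124 higher and 162 lower probes, against 21.3 and 25.5 for independent lists, with 4 opposite. When only the nitrate and pyruvate groups of the mutant were fitted, 390 were called.

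The NO and nitrate responses of wild type were set against each other. Of the probes called, 96 rose and 144 fell in both, against 24.3 and 62.8 for independent lists, and 22 went opposite ways. The 2 responses correlated with r = 0.67 (rho 0.34), with a covariance of 0.35. Both use the same pyruvate arrays, and simulated unchanged groups against shared controls gave r = 0.51 but a covariance of 0.02. At most 1 probe was called the same way in both in any of 100 simulations. With no probe changed, hardly any could be called, so that count does not show how many shared calls come from the shared arrays. The 3 control arrays were not split, since 1 part would hold a lone array, and part of the excess of shared calls may come from them. Taking the NO response from wild type and the nitrate response from the mutant, which share no array, r was 0.49, and for the converse pair 0.43. A set of 58 probes rose at least 2-fold under both in wild type. Their group medians were −2.63 in pyruvate, 0.65 with NO and 0.32 in nitrate. In the mutant the medians of the same 58 were −1.47, 0.43 and 0.18.

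**Figure D2:**
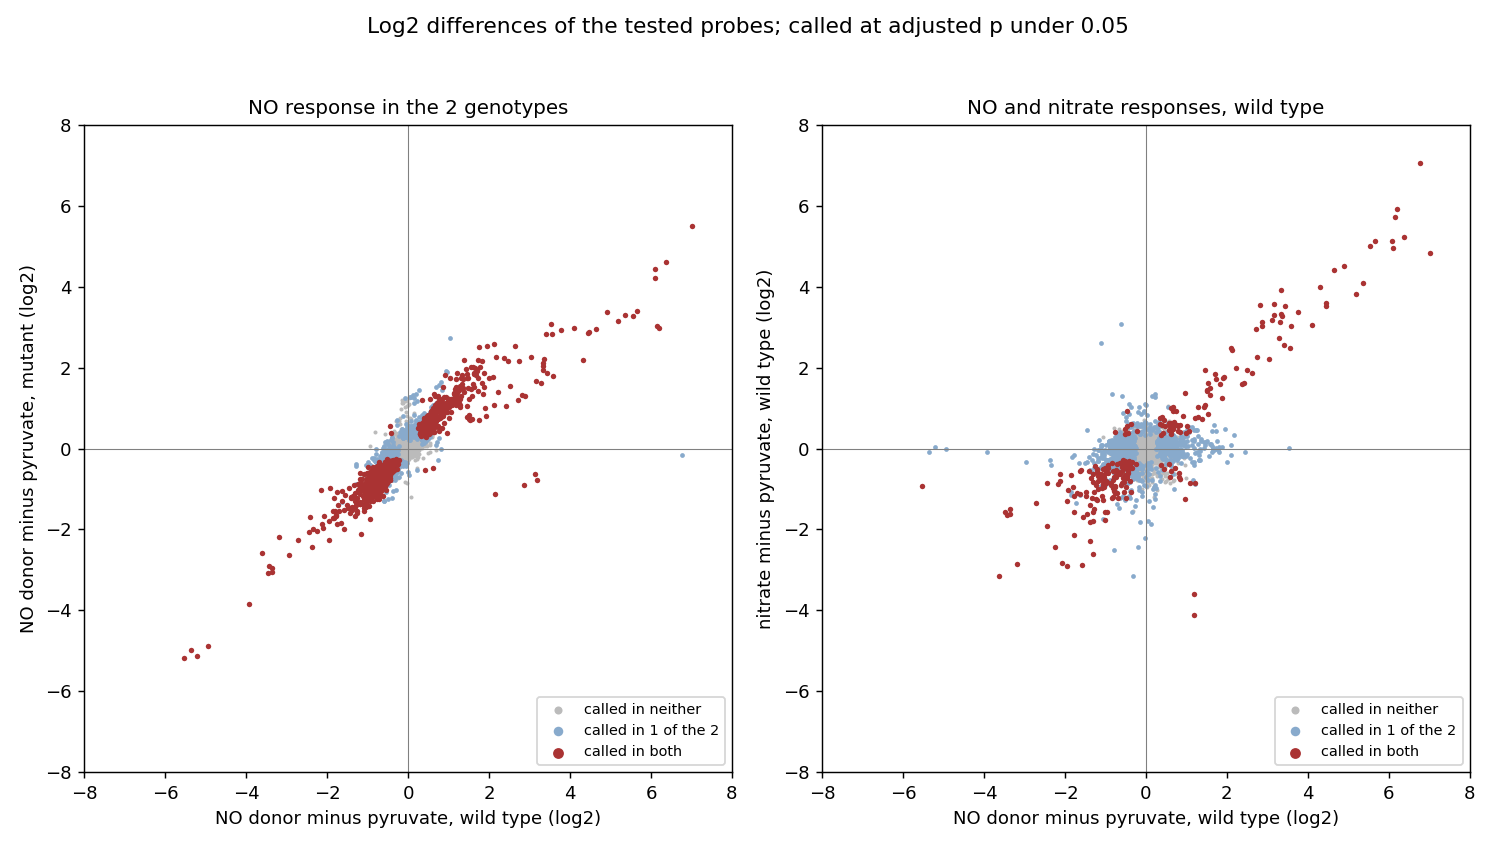
Log2 differences of the tested probes, each point a probe, coloured by whether it was called in both, 1 or neither comparison. Left, the NO response in the mutant (vertical) against that in wild type (horizontal), r = 0.88; right, the nitrate response (vertical) against the NO response (horizontal) in wild type, r = 0.67.

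Under NO or nitrate few probes were called between the genotypes. In nitrate 3 probes were called: BSO8-3538 was higher in the mutant by 2.13 ± 0.32 (SE, adjusted p = 0.0104, and 0.0676 to 0.104 without wild-type array 2 or 3 or mutant array 3). BSO8-2159 was lower, at −2.87 ± 0.25 (SE, adjusted p = 1.08e-05), as was BSO8-2877, at −1.36 ± 0.24 (SE, adjusted p = 0.0491, and 0.0634 with the arrays centred and 0.0501 to 0.165 without any 1 array of these groups other than mutant array 1). BSO8-2877 had values on only 2 mutant nitrate arrays, so without 1 of these that group held a lone value. With NO 1 probe was called, BSO8-2159, at −3.52 ± 0.25 (SE, adjusted p = 5.65e-07). An unadjusted p under 0.05 was found for 407 probes in nitrate and 330 with NO, against 938 in pyruvate and 138 expected if no probe differed. The groups did not overlap on any array at 745 of the 2765 probes in nitrate and 554 with NO. Chance gives 10% for probes with 3 values against 3, and more where values are missing. The median of all probes was also lower in the mutant, by a shift of −0.10 in nitrate and −0.08 with NO. Such a shift can raise these counts and those of unadjusted p. A low number of calls thus does not show that the genotypes were alike, and these counts do not measure how far they differed. After centring, 6 probes were called in nitrate (5 higher, 1 lower) and 1 with NO. In nitrate quantile normalization gave 18 and a replicate block 10, and leaving out single arrays 1 to 14, the 14 without mutant array 1. With NO array quality weights gave 10, and leaving out single arrays 1 to 6, the 6 without wild-type array 1 or 2. BSO8-2159 was lower in all 9 mutant arrays than in any wild-type array by at least 2.28.

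The difference itself was tested as the effect of NO, or of nitrate, in the mutant minus that in wild type. For NO 35 probes were called, 31 with a smaller or reversed effect in the mutant and 4 higher, and for nitrate 41, of which 31 were lower and 10 higher. In each case the 31 were called higher with that treatment in wild type. BSO8-585 had the strongest interaction in both, at −6.94 ± 0.24 for NO and −7.12 ± 0.24 for nitrate (SE, adjusted p = 1.92e-11 and 1.29e-11); for NO the median of all probes was 0.10, and with the arrays centred the value was −7.06. BSO8-827 followed for NO at −3.95 ± 0.22 (SE, adjusted p = 3.22e-09) and BSO8-828 for nitrate at −3.89 ± 0.16 (SE, adjusted p = 1.43e-10). On the other side BSO8-1282 had an NO interaction of 1.00 ± 0.20 (SE, adjusted p = 0.0273, and 0.0602 with a replicate block) and BSO8-3250 a nitrate interaction of 2.21 ± 0.36 (SE, adjusted p = 0.00563). BSO8-1282 had only 2 values in the mutant in pyruvate and 2 with NO. BSO8-3250 had 2 values each in wild-type pyruvate, mutant pyruvate and mutant nitrate cultures. With the arrays centred the calls were 44 for NO (2 higher, 42 lower) and 38 for nitrate (3 higher, 35 lower). A replicate block within genotype gave 64 for nitrate. Quantile normalization left 9 and 16, and leaving out the rounded arrays left 20 and 9, the latter with a lone wild-type nitrate array assumed to vary like the other groups.

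Of the 31 probes lower in each interaction, 26 were common to both, and all 26 were called higher in the mutant in pyruvate. Their median levels in wild type were −3.10 in pyruvate, 0.59 with NO and 0.31 in nitrate. In the mutant they were −1.47, 0.50 and 0.14. All these contrasts use the same wild-type pyruvate arrays, so they are not independent. Both interactions and the mutant contrast in pyruvate share the mutant pyruvate arrays as well. The pyruvate difference between genotypes enters each interaction with its sign turned. Few probes were called between genotypes under NO or nitrate, so the overlap and the higher calls of all 26 were largely set by the selection. The 26 were divided, after the data were seen, by whether they were called higher with NO in the mutant. The mutant pyruvate level enters that call, so the medians below describe the division and do not test for separate kinds. In the mutant 7 probes, BSO8-585 and BSO8-827 among them, were not called higher with NO, and 5 of the 7 were called lower with NO and 4 lower in nitrate. The median of the 7 was 0.59 in mutant pyruvate cultures and −0.02 with NO, against −2.74 and 0.12 in wild type. The other 19 were still called higher with NO in the mutant. Their median was −2.02 in mutant pyruvate cultures, between the −3.80 of wild type and the 0.72 reached with NO in the mutant. Of the 37 probes at least 2-fold higher in the mutant in pyruvate, 31 were called higher both with NO and with nitrate in wild type. Calls higher in the mutant in pyruvate and higher in wild type were shared by 48 probes for NO (11.2 for independent lists) and 50 for nitrate (4.77). Calls lower in both were shared by 123 (89.1) and 46 (34.7), and 46 and 25 probes were called in opposite directions. With the arrays centred the shared rises were 58 (21.6) and 66 (8.35), the shared falls 14 (7.50) and 12 (3.71), and 31 and 22 went opposite ways. The correlation over all probes was r = 0.38 in each case (rho 0.10 for NO and 0.02 for nitrate). Simulated unchanged groups gave r = 0.51, or 0.46 when same-numbered arrays of 1 genotype were simulated as correlated, and the covariance with NO was 0.13 against 0.02 in both simulations.

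**Figure D3:**
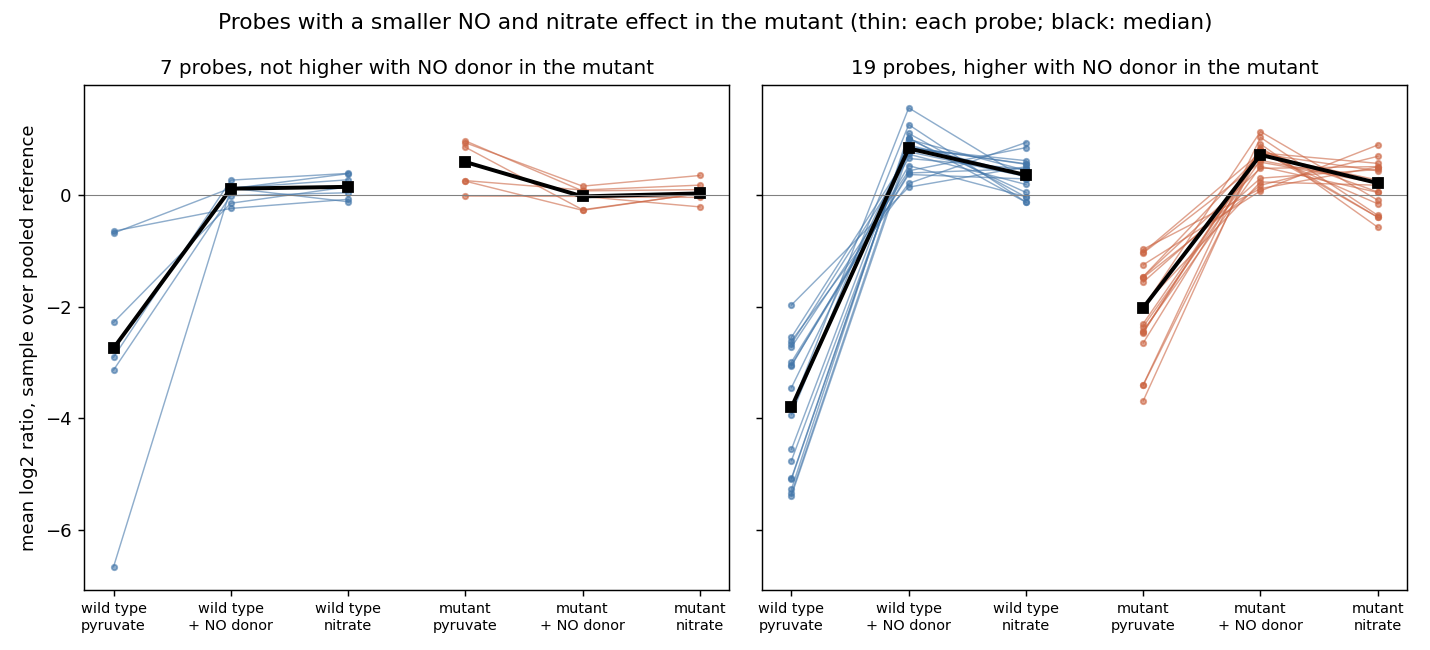
Mean log2 ratio over the pooled reference (vertical axis) in each genotype and treatment (horizontal axis) for the 26 probes with smaller NO and nitrate effects in the mutant. Thin lines are probes and black lines medians; the panels divide the probes by their call with NO in the mutant, and 7 probes in the left panel have a mutant pyruvate median of 0.59, and 19 in the right panel one of −2.02.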

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

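The tests of array offsets, of admixed RNA and of exchanged arrays were chosen after the results were seen. The effect of NO differed between genotypes at 35 probes and that of nitrate at 41, by the test of the difference. On the side of a smaller effect in the mutant the strongest were BSO8-585 (−6.94 for NO, −7.12 for nitrate), BSO8-827 (−3.95 for NO) and BSO8-828 (−3.89 for nitrate). Other probes named in the report were called on this side as well: BSO8-827 for nitrate (−3.88), BSO8-828 for NO (−3.77), BSO8-333 (−3.22 and −3.32), BSO8-2450 (−1.77 and −2.12) and BSO8-2451 (−1.67 and −1.91) for NO and nitrate, and BSO8-1762 for nitrate (−1.97). On the other side were BSO8-609 (1.13) and BSO8-1282 (1.00) for NO, and BSO8-3250 (2.21) and BSO8-515 (1.51) for nitrate. BSO8-1282 and BSO8-3250 had only 2 values in some of the groups compared. BSO8-609 and BSO8-515 lost their call after median centring (adjusted p = 0.0724 and 0.0716).

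The first pattern is that the mutant differed from wild type at many probes in pyruvate cultures, while few were called with NO or nitrate. RNA from NO-exposed cells in the mutant pyruvate samples would move every probe by 1 common share. The share was counted, in linear ratios, on the way from the wild-type pyruvate level to the wild-type NO level. For the 31 probes higher both in the mutant in pyruvate and with NO and nitrate in wild type, it ran from 2.02% to 231%. The lowest array of the highest probe lay 69.2 times above the highest array of the lowest, against a single admixture as the only cause at all 31 probes. In this range 5 probes had shares of 112% to 231%, and the other 26 shares of 2.02% to 27.7% (median 9.21%), with a ratio of 8.98 found in the same way. Such ratios cannot exclude an admixture that acts beside other changes at these probes. An exchange of some arrays between genotypes was tested with the probe of the widest gap between genotypes on the arrays of 1 treatment alone. On the NO arrays and on the nitrate arrays this was BSO8-2159, which on the 12 arrays of the other treatments still parted the genotypes in the same direction, by gaps of 2.28 and 2.48 (log2), against such an exchange. On the pyruvate arrays it was BSO8-585, which rose with both treatments in wild type and did not part the other arrays (a gap of −0.59). An exchange of all labels would leave these gaps in place and stays open, because nsrR itself could not be looked up. The loss of nsrR, which the design names, and growth differences between the genotypes stay open and untested.

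How far regrouping of arrays could give such counts was tested as well. For the interactions, 5 of 100 exchanges of genotype labels within treatments called at least the 35 probes for NO (highest other 185), and 9 of 100 at least the 41 for nitrate (highest other 137), so the share over all exchanges does not exclude chance. The high counts point to a structure of the arrays: each exchange that reached the real count left the pyruvate arrays of both genotypes intact, and so kept the genotype difference in pyruvate, which is part of the interaction itself. Such exchanges are not free of the effect, and their number says little about chance. The 92 and 89 exchanges that mixed those arrays put that difference into the spread, which lowers their counts (highest 10 and 33), so they do not exclude chance either. Exchanges were drawn separately for each treatment, so they could also part same-numbered arrays of 1 genotype, which were paired. For comparisons of 3 against 3 arrays, 10 splits exist, too few for a share under 0.05. In pyruvate the real split called 447 and the highest other 0 (1 of 10 as large). In nitrate, 2 of 10 were as large, the real one with 3 and another with 16, which set wild-type arrays 1 and 2, both rounded, and mutant array 3 against the rest. With NO, 2 of 10 were as large, the real one with 1 and another with 13. Both of these other splits mixed the genotypes, and why they called more probes than the real ones was not tested. NO against pyruvate gave 1065 against 3 in wild type and 1149 against 1 in the mutant. Nitrate against pyruvate gave 429 against 0 and 620 against 1, and NO against nitrate 981 against 1 and 1084 against 2.

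The second pattern is that far more probes were lower than higher in the mutant in pyruvate, 369 against 78. After each array was centred on its median 27.5% of the calls were lower, and of the changes of at least 2-fold 37 rises and 36 falls became 44 and 6. Centring moves all differences up together, so offsets left by the normalization and a true broad shift would both give this, and they cannot be told apart from ratios that have no external standard. The imbalance also depended on the arrays used, with 46 higher and 45 lower without the 3 rounded arrays, 59 and 86 without wild-type pyruvate array 1, and 64 and 148 with rounding as a block; why was not tested.

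Signals also appeared among probes left out of the main test for missing values in other groups. With 2 values needed only in the groups compared, 74 of 389 further probes were called in the mutant in pyruvate, all lower, in the direction of the shift of the median. For NO against pyruvate 68 of 406 were called in wild type (6 higher, 62 lower) and 32 of 318 in the mutant (21 higher, 11 lower, the strongest rise 4.02).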

How the results depend on the processing

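Fits by rounding, the block within genotype, the looser rule on missing values, NO against nitrate and the correlations of responses without single arrays were chosen after seeing the data. None of the 4 correlations of responses that were rerun changed direction. Nor did any named probe under median centring, quantile normalization, either replicate block or the loss of single arrays. Named probes were not rerun under the other alternatives. Median centring turned the balance of higher to lower calls from 78 to 369 into 116 to 44 (mutant in pyruvate), from 1 to 2 into 5 to 1 (mutant in nitrate), from 397 to 668 into 516 to 471 and from 580 to 569 into 575 to 592 (NO in wild type and mutant), from 349 to 271 into 280 to 325 (nitrate in mutant), and from 420 to 561 into 535 to 457 and from 483 to 601 into 545 to 538 (NO against nitrate). Of 104 recounts of the planned comparisons with all or other sets of arrays, 79 stayed within 1.5 times, as did 19 of 22 for NO against nitrate, and 121 of 128 tests of named probes kept their call. Below, some lower counts come from fits with fewer probes or arrays, and the cause of the changed counts was not tested. For the mutant in pyruvate (447), calls numbered 160 with median centring, 81 with quantile normalization, 248 with the 1836 probes measured on all arrays, 186 with only the compared groups, 212 with rounding as a block and 91 without the rounded arrays. In nitrate (3) they were 6, 18 and 1 for the first 3 of these, 10 with a replicate block and 5 with a replicate block within genotype. With NO (1), 2 were called after quantile normalization and 10 with array quality weights. NO in wild type (1065) fell to 683 without the rounded arrays. Nitrate in wild type (429) gave 701 with array weights, 175 without the rounded arrays, 136 with only the rounded and 192 with only the unrounded ones, each of these 3 with a lone array on 1 side, assumed to vary like the other groups; in the mutant (620) only the compared groups gave 390. The NO interaction (35) gave 9 with quantile normalization, 53 with array weights and 20 without the rounded arrays; the nitrate interaction (41) gave 16, 64 with the block within genotype, and 9 without the rounded arrays, again with a lone nitrate array. The block within genotype moved no other planned count by over 1.5 times. Leaving out each array, with the spread pooled, gave 145 to 510 for the mutant in pyruvate, 1 to 14 in nitrate and 1 to 6 with NO. The ranges were 791 to 1057 and 958 to 1080 for NO in wild type and mutant, 298 to 373 and 456 to 525 for nitrate, and 19 to 47 and 25 to 52 for the interactions. For the mutant in pyruvate the count was 145 without wild-type pyruvate array 1, 189 without array 2, and 252 and 267 without mutant pyruvate arrays 1 and 3. In nitrate it was 1 without wild-type arrays 2 or 3 or mutant array 3 and 14 without mutant array 1. With NO it was 6 without wild-type arrays 1 or 2 and 2 without mutant arrays 2 or 3. The NO interaction gave 21 without wild-type pyruvate array 2, 23 without mutant pyruvate array 3 or mutant NO array 2, and 19 without mutant NO array 3; the nitrate interaction 25 without wild-type nitrate arrays 2 or 3 and 27 without mutant nitrate array 3. Correlations of responses ranged from 0.65 to 0.69 (NO and nitrate, wild type), 0.86 to 0.88 (NO in both genotypes), 0.72 to 0.76 (nitrate in both) and 0.31 to 0.42 (mutant in pyruvate and NO). Calls of BSO8-2877, BSO8-3538, BSO8-609, BSO8-1282 and, for the nitrate interaction, BSO8-515 were lost without some array. Gene lists and averages of probes per gene were not run, for lack of gene names. Signal over background was not given in the sources used here, so what it limits is unknown.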

Other observations

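The comparison of NO against nitrate was added after the data were seen. Added NO and nitrate respiration were also compared directly, and many probes differed. The NO cultures also held 0.5% glucose and 0.5% pyruvate and the nitrate cultures 1% glucose and no pyruvate, so these differences include any effect of the carbon source. In wild type 981 probes were called, 420 higher and 561 lower with NO than in nitrate, with 120 and 72 at least 2-fold, and in the mutant 1084, 483 higher and 601 lower. BSO8-3318 and BSO8-3319 were higher with NO by 5.30 ± 0.21 and 4.78 ± 0.28 (SE) in wild type and by 5.36 ± 0.21 and 4.80 ± 0.28 in the mutant. BSO8-822 and BSO8-820 were lower with NO, with differences of −5.28 ± 0.34 and −5.23 ± 0.35 in wild type and −4.96 ± 0.34 and −5.13 ± 0.35 in the mutant (limma adjusted p at most 5.35e-08 for all 8). The first pair was near the pool in pyruvate (−0.20 and −0.26 in wild type) and low in nitrate (−4.30 and −3.86). The second was high in pyruvate (0.70 and 0.88) and in nitrate (0.62 and 0.91) and low with NO (−4.66 and −4.33). Of the 133 probes that rose at least 2-fold with NO in wild type, 64 were called higher with nitrate and 4 lower, and of the 126 that fell, 72 were called lower and 0 higher. With the arrays centred the direct comparison called 992 in wild type, 535 higher and 457 lower, and 1083 in the mutant, 545 higher and 538 lower.

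A further 6 of the 37 probes at least 2-fold higher in the mutant in pyruvate were not called higher with both NO and nitrate in wild type. Their medians were 1.06 in the mutant and −0.18 in wild type in pyruvate. With NO the medians were −0.35 in the mutant and −0.77 in wild type, and in nitrate −0.89 and −1.81.

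Probes with consecutive ID numbers changed together. Over 2071 such pairs the log2 differences for NO in wild type correlated with r = 0.52, against at most 0.075 in 1000 shufflings, and r fell to 0.05 at a distance of 5 and 0.00 at 50. Of the 133 probes at least 2-fold higher, 65 lay in runs of consecutive IDs, with a mean of 9.54 for random sets. Noise shared by neighbours within an array is a technical explanation, and deviations from the group means did correlate between neighbours (0.24 to 0.36 in wild-type arrays, 0.37 to 0.59 in mutant arrays). For NO in wild type the covariance of neighbours was 31.6 times what those deviations give (95% bootstrap interval 23.1 to 42.0). This argues against noise that varies between replicate arrays as the whole of it. For the mutant in nitrate it was 1.43 times (1.09 to 1.89), which such noise alone may nearly give. Noise common to all arrays of a group does not enter those deviations, so it was not tested. The bootstrap drew pairs as independent though neighbouring pairs share a probe, so the intervals may be too narrow. Whether consecutive IDs stand for genes that lie or are transcribed together was not tested, because the IDs were not paired with genes.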
